A study of Mus musculus with 6 samples.

How the data were processed

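Total RNA from the striatum of 6 mice (3 Hdh4/Q80, 3 wild-type littermates) was extracted with TRIzol and column cleanup, labelled with biotin by in vitro transcription and hybridised to Affymetrix mouse arrays, 1 array per mouse, per the labels' protocols. The design text counts 3 mice per group, so each array was taken as 1 mouse; no batch or date is labelled. Zygosity of the mutants is not given in the sources used here. Groups and replicate numbers (4 to 6 wild type, 7 to 9 Hdh4/Q80) were taken from the sample titles. The deposited values are log2 expression per probe set, made by the authors with robust multi-array average (RMA) in the affy package, per the submitters' processing notes; package versions and which arrays were normalized together are not given in the sources used here. RMA corrects background, equalises the distribution of probe intensities between arrays and summarises the probes of a set on the log2 scale. It therefore removes any global change in RNA amount and shrinks fold changes of dim and of nearly saturated probe sets. The values ran from 2.57 to 14.24 with 0 missing, and no scanner files, detection calls or background measures were used here, so no probe set could be called absent. Precision is limited by the number of arrays.

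All 12488 probe sets of the deposited table were read, and 66 control probe sets were left out of the tests. Names came from a platform annotation: 10833 probe sets had 1 gene symbol, 396 several and 1193 none. Genes were named only from the first kind; 8237 of 8251 genes matched the reference gene table (mouse assembly GRCm38.p6) by gene identifier, with the same symbols. That table was used only for names and gene order. Where a gene had several probe sets, the one with the highest mean over all 6 arrays stood for it. Probe sets with an _f_at, _s_at, _i_at or _r_at suffix can bind related transcripts or have fewer specific probes.

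Hdh4/Q80 was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options, 4 residual and 5.81 prior degrees of freedom), with Benjamini-Hochberg adjustment over the 12422 probe sets and a threshold of 0.05. Differences are mutant minus wild type on the log2 scale, given with limma's standard error or 95% interval. A total of 20 gene lists (348 entries, 246 of them measured) covering striatal neuron classes, transmission, stress, metabolism, glia, vessels, blood and neighbouring brain tissue were tested with camera at a preset correlation of 0.01, with the correlation estimated, and with fry, adjusted over the lists. Calls were counted over all probe sets and adjusted over each list alone. A list's shift is relative to other genes on the arrays for camera. The lists, the tests, the rule for named genes and the alternatives were set before the data were examined, apart from those named as later choices. The rule named Htt, up to 10 genes per direction past the threshold or, since fewer than 5 passed, the 5 named genes of smallest p in each direction, up to 4 members of smallest p per list (the text gives those that carry each account) and a fixed panel of 12 genes, of which 1 is not reported here; Ttr, Mbp, Foxj1, Rfc1 and Fos fall outside the rule and were chosen after their values were seen.

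Alternatives were leaving out the dimmest 40% of probe sets, median centring, renewed quantile normalization, cyclic loess, trended and robust moderation, array weights, the mean of a gene's probe sets, and leaving out each mouse. The array weights rested the mutant side mainly on Hdh4/Q80 replicate 7 (6.18, against 0.228 and 0.405 for replicates 8 and 9). Neighbours of Htt were compared with other genes by Fisher's exact test. Group differences in array quality were tested by exact permutation over the 20 ways to choose 3 of 6 arrays. The fit was tested on simulated data of 12422 probe sets with the fitted spread: with 200 probe sets changed at each of 3 sizes it called 45.5% for a change of 25%, 94% at 1.5-fold and 99% at 2-fold, with 32 false calls; with 20 at each size it called 0%, 75% and 95%. The simulation assumes independent probe sets, which real arrays do not have. It also gives a probe set the same spread on all 6 arrays, whereas the real arrays differed in spread. The SD of deviations from the gene means was 0.0684 in Hdh4/Q80 replicate 7 and 0.17 in replicate 8.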

Results

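Messenger RNA from the striatum, the forebrain region that degenerates first in Huntington's disease, was measured on 6 Affymetrix arrays, 1 per mouse. The samples came from 3 Hdh4/Q80 mice and 3 wild-type littermates, all female, C57BL/6 and 12 months old by the labels. Hdh4/Q80 mice carry an expanded CAG repeat in the mouse huntingtin gene (Htt, formerly Hdh), which lengthens the glutamine tract of the protein. The comparison asks which striatal transcripts differ in level between the mutants and their littermates. Each array gave a log2 expression value for 12422 probe sets after removal of the manufacturer's controls, and 10833 of these name exactly 1 gene, 8251 genes in all. Array medians lay between 7.11 and 7.13, and pairs of arrays correlated at r = 0.990 to 0.998 across probe sets, which are not independent replicates. Hdh4/Q80 replicate 8 stood apart: its mean correlation with the other arrays was 0.992, against 0.995 to 0.997 for the remaining 5 mice, and it held the extreme score (19.95) on the first principal component, which carried 50.9% of the variance. All 6 arrays had Xist between 9.26 and 9.73, and the measured Y-linked genes Kdm5d, Uty and Eif2s3y stayed at or below 5.37, so no array went against the labelled sex.

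Htt itself was measured by a pair of probe sets. The brighter one read 10.35 ± 0.0547 in wild type and 10.32 ± 0.0728 in Hdh4/Q80 striatum (mean log2 ± SD, n = 3 mice each), a difference of -0.03 with a 95% interval of -0.19 to 0.13. The other read 8.46 ± 0.036 and 8.34 ± 0.12, a difference of -0.12 with an interval of -0.30 to 0.05. Neither passed limma's test (adjusted p = 0.953 and 0.857). Where these probe sets lie relative to the repeat is not given in the sources used here, so the Htt values do not check the genotype.

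No transcript passed the test between Hdh4/Q80 and wild-type striatum. Of 12422 probe sets, 0 reached an adjusted p under 0.05 in limma's moderated test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.857. At an unadjusted p under 0.05 there were 634 probe sets, 360 higher and 274 lower in the mutants, where chance alone gives 621. At an unadjusted p under 0.001 there were 8, against 12.4 by chance. By gene, 355 of 8251 had an unadjusted p under 0.05 (179 higher, 176 lower), against 413 by chance. The split by probe set moved with the setting. It was 320 higher and 299 lower after quantile normalization, 505 and 544 without Hdh4/Q80 replicate 7, and 320 and 180 without replicate 8. The 3 mutants lay entirely above or entirely below the 3 wild types for 11.7% of probe sets, where chance gives 10%. The measured differences were small: the median absolute difference between groups was 0.07 on the log2 scale, 6 probe sets differed by more than 1.5-fold and 1, for Ttr, by more than 2-fold. For 98.7% of probe sets the 95% interval of the difference excluded a 1.5-fold change in either direction, and for 99.9% it excluded a 2-fold change. Data were also simulated with the fitted spread, taken as equal on the 6 arrays, and 60 probe sets were changed. There the test called 19 of 20 with a 2-fold change, 15 of 20 with a 1.5-fold change and 0 of 20 with a change of 25%. RMA values understate true fold changes, so these limits refer to the array scale.

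The measured panel genes of the striatum's principal neurons had small mean differences on their brightest probe sets, and none passed the test. Penk, the enkephalin precursor of indirect-pathway spiny neurons, read 13.02 ± 0.111 in wild type and 13.04 ± 0.0966 in Hdh4/Q80 mice, a difference of 0.02 with a 95% interval of -0.17 to 0.20. This probe set lay near the highest value on the arrays (14.24). RMA shrinks fold changes of nearly saturated probe sets, so its interval may be a weak limit. The other Penk probe sets, at 8.837 and 3.469 in wild type, had differences of -0.19 (interval -0.48 to 0.11) and -0.12. The second of these was dim. Drd2, the D2 dopamine receptor, differed by -0.06 (interval -0.30 to 0.18) and Tac1, the substance P precursor of direct-pathway neurons, by 0.02 (-0.32 to 0.35). Pdyn, the dynorphin precursor, differed by 0.08 (-0.07 to 0.23), with the opposite sign on its second probe set (-0.07). Cnr1, the CB1 cannabinoid receptor, differed by -0.06 (-0.36 to 0.24) and Rgs9, a striatum-enriched regulator of G-protein signalling, by 0.11 (-0.06 to 0.28). The Rgs9 probe set was dim, at 5.577 in wild type and 5.685 in mutants, below the lower quartile of each array (5.79 to 5.86). RMA shrinks fold changes of dim probe sets, so the Rgs9 interval is a weak limit. All of these genes had adjusted p-values of 0.857 or more in limma's test. Each of these intervals excludes a change of 1.5-fold on the array scale, but smaller changes are not excluded. Drd1, Adora2a, Ppp1r1b and Pde10a, also fixed for description, had no probe set assigned to them alone and were not analysed here.

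**Figure D1:**
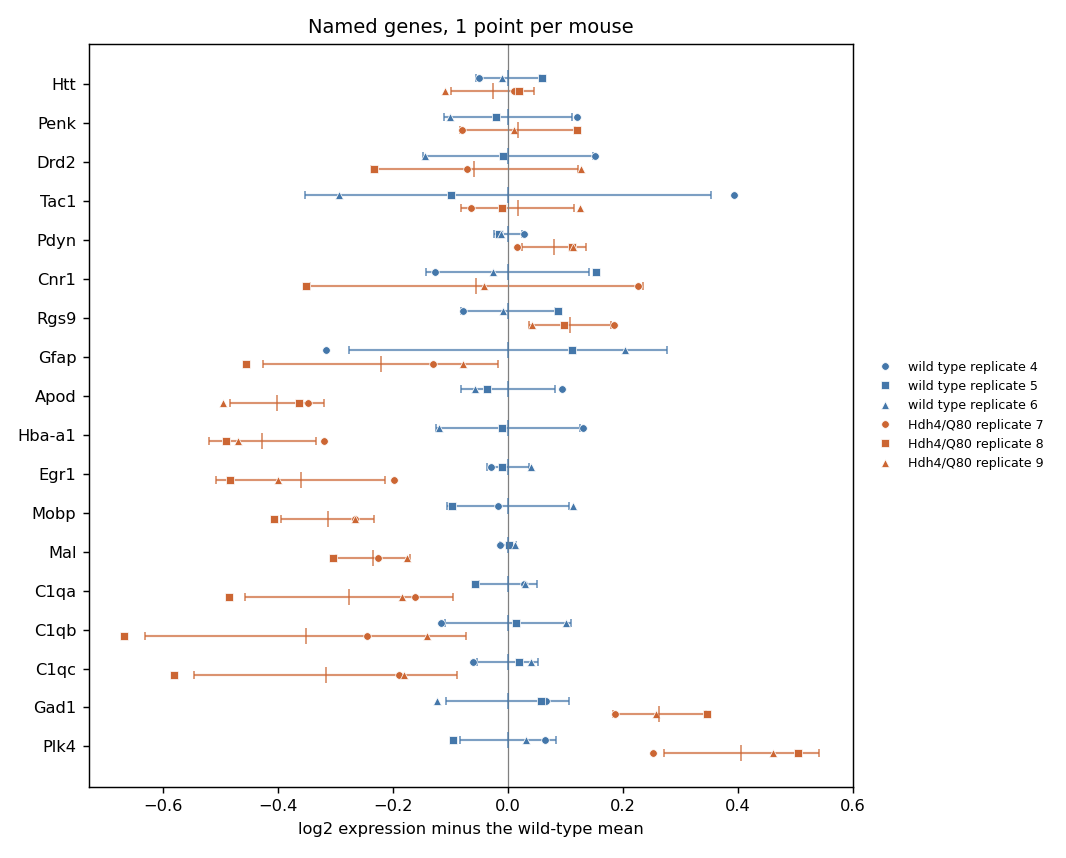
Log2 expression of 18 named genes in each mouse, minus the wild-type mean of that gene, from each gene's brightest probe set; the genes were picked for display from those named by rule after their values were seen. Blue points are wild-type and orange points Hdh4/Q80 mice, ticks with bars are the group mean ± SD (n = 3), and striatal genes such as Penk, Drd2 and Tac1 overlap between groups, whereas the 3 mutants lie below all wild types for Apod (-0.40) and above them for Plk4 (0.41), neither of which passed the adjusted test.

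Among the lists of neuronal genes, 16 measured markers of spiny projection neuron identity and signalling had a median difference of -0.08, with 12 below 0 and 0 passing the test over all probe sets or adjusted over the list alone. A dim probe set of Ptpn5, at 4.948 in wild type and 5.191 in mutants, had the opposite sign (0.24). The members with the smallest p-values were Rxrg, a retinoid receptor (-0.22 ± 0.12, SE), Rgs4 (-0.23 ± 0.127), Ptpn5, the striatum-enriched phosphatase STEP (-0.21 ± 0.134), and Arpp19 (-0.16 ± 0.107; -0.045 on its other probe set). With 1 mouse left out these ran from -0.32 to -0.11 (Rxrg), -0.39 to -0.12 (Rgs4), -0.30 to -0.059 (Ptpn5) and -0.24 to -0.029 (Arpp19). The list did not pass limma's camera test against other genes (adjusted p = 0.0956), and its mean difference of -0.077 became -0.0058 without Hdh4/Q80 replicate 8, -0.040 without wild-type replicate 4, -0.050 after cyclic loess, 0.0022 with array weights and -0.12 without Hdh4/Q80 replicate 9. Without wild-type replicate 6 it passed (adjusted p = 0.00315, mean -0.12; adjusted p = 0.515 with an estimated correlation). The 7 measured direct-pathway markers had a median of 0.02 (adjusted p = 0.693) and the 3 indirect-pathway markers -0.06 (adjusted p = 0.528). The indirect-pathway mean difference of -0.051 became -0.013 after quantile normalization, -0.016 after cyclic loess and -0.026 without wild-type replicate 4. With the mean of each gene's probe sets it became -0.089. Of the 10 interneuron markers, Sst, the somatostatin precursor, had the smallest p (-0.20 ± 0.118; -0.28 to -0.057 with 1 mouse left out) and the list had a median of -0.02 (adjusted p = 0.725). In the list of glutamate and GABA transmission, Gad1, which makes GABA, read 10.45 ± 0.108 in wild type and 10.71 ± 0.0825 in mutants (a difference of 0.26 ± 0.0806, SE; unadjusted p = 0.00862 and adjusted p = 0.857 in limma's test). Gria3 (-0.29 ± 0.108), Gria1 (-0.22 ± 0.109) and Camk2a (-0.42 ± 0.242) had negative differences. Another probe set of Gria1 differed by -0.0020, and with 1 mouse left out Gria3 ran from -0.41 to -0.20, Gria1 from -0.32 to -0.086 and Camk2a from -0.67 to -0.24. In this list 12 of the 17 measured members were below 0 (median -0.10, adjusted p = 0.0956). Of 15 ion channel genes 13 were below 0 (median -0.08, adjusted p = 0.0615), with Ryr1, a calcium release channel, at -0.33 ± 0.13 (-0.44 to -0.19 with 1 mouse left out). The transmission and channel lists passed without wild-type replicate 6 (adjusted p = 0.0417 and 0.00328) or Hdh4/Q80 replicate 7 (0.0105 and 0.0319), and the channel list with the mean of each gene's probe sets (0.0454). With an estimated correlation these passes were lost (adjusted p = 0.535 and 0.515 without wild-type replicate 6, 0.546 for both without Hdh4/Q80 replicate 7, and 0.563). The transmission list's mean difference of -0.087 became -0.025 without Hdh4/Q80 replicate 8 (adjusted p = 0.831), 0.028 with array weights and -0.15 without Hdh4/Q80 replicate 7. The channel list's, -0.072, became -0.044 without Hdh4/Q80 replicate 8 (0.257), -0.038 without wild-type replicate 4 (0.452) and 0.00021 with array weights. In these lists 0 genes passed adjusted over the list alone.

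Ranked on each gene's brightest probe set, the 5 genes with the smallest p-values in each direction had differences of less than 1.5-fold. None of them passed the adjusted test. Dimmer probe sets were left out of this ranking. Those of Gtf3a (0.62 ± 0.13 log2, SE) and Pdia6 (-0.38 ± 0.088), among others, had smaller p-values than some of the genes named here. On the lower side, Apod, an apolipoprotein made by glia, read 10.35 ± 0.0794 in wild type and 9.95 ± 0.083 in Hdh4/Q80 mice, 1.32-fold lower (SE 0.08 log2). Hba-a1, alpha-globin, was 1.34-fold lower (11.64 ± 0.124 against 11.21 ± 0.0894), the linker histone H1f2 was 1.27-fold lower and the activity-induced transcription factor Egr1 1.28-fold lower (10.07 ± 0.0324 against 9.71 ± 0.147). Rala, a small GTPase, was 1.33-fold lower on this probe set and differed by 0.01 log2 on its other one. On the higher side, Plk4, the centriole duplication kinase, was 1.32-fold higher (6.08 ± 0.0839 against 6.49 ± 0.135). Rpp30, a ribonuclease P subunit, was 1.27-fold higher, but differed by -0.01 log2 on its other probe set, and Spata6, Col5a1 and Cyp3a13 were 1.24, 1.21 and 1.23-fold higher (0.13 log2 on the other probe set of Col5a1). In all 10 genes the 3 mutants lay on one side of the 3 wild types, and all 10 had an adjusted p of 0.857 in limma's test.

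The microglia and oligodendrocyte lists were shifted down in the mutants with camera's preset correlation, and neither was called with an estimated one. All 3 measured C1q complement genes, which microglia express, were among the smallest p-values of the microglia list: C1qc read 10.27 ± 0.0539 in wild type and 9.95 ± 0.228 in Hdh4/Q80 mice, C1qa 9.51 ± 0.05 and 9.24 ± 0.181, and C1qb 8.81 ± 0.109 and 8.46 ± 0.279. Tyrobp, a microglial signalling adaptor, differed by -0.21 ± 0.0885 (SE). Hdh4/Q80 replicate 8 was the lowest mouse for C1qc (9.69, against 10.08 and 10.09 in replicates 7 and 9), and without it the differences became -0.19 for C1qc, -0.17 for C1qa, -0.19 for C1qb and -0.12 for Tyrobp. A dimmer probe set of C1qb had the opposite sign (0.24). Of 11 measured members 10 were below 0 and 0 passed adjusted over the list alone (smallest adjusted p = 0.0747). Against other genes the microglia and complement list was shifted down (camera adjusted p = 0.0101, median -0.07), a call lost with an estimated correlation between members (adjusted p = 0.619) and without Hdh4/Q80 replicate 9 (adjusted p = 0.0503). Without Hdh4/Q80 replicate 8 the list was still called (adjusted p = 0.0153), while its mean difference went from -0.13 to -0.075; with array weights the mean was -0.080. The oligodendrocyte and myelin list was also shifted down (adjusted p = 0.0255, median -0.08, 9 of 11 members below 0). This call was lost with an estimated correlation (adjusted p = 0.619), without wild-type replicate 6, Hdh4/Q80 replicate 7 or replicate 9 (adjusted p = 0.126, 0.0593 and 0.251), after quantile (0.101) or cyclic loess (0.145) normalization, and with the mean of each gene's probe sets (0.0597). Its mean difference of -0.085 became -0.056 after cyclic loess. Its members Mobp, a myelin protein, at 12.17 ± 0.103 against 11.86 ± 0.0808, and Mal, another myelin protein, at 9.18 ± 0.0131 against 8.95 ± 0.0647, were the 2 that passed when adjusted over the list alone (adjusted p = 0.0324 and 0.0343); neither passed over all probe sets. The remaining probe sets of Mobp differed by -0.51, -0.50 and -0.15. Mbp, the major myelin basic protein, had a difference of 0.01, and Cnp and Sox10 had differences of 0.12 and -0.11. The Cnp probe set was dim, at 5.616 in wild type and 5.74 in mutants. Both means lay below the lower quartile of each array (5.79 to 5.86), so the Cnp difference says little. Within the list, the Mobp call ended without wild-type replicate 4 or 6 (adjusted p = 0.0956 and 0.15) or Hdh4/Q80 replicate 7 or 8 (0.0724 and 0.0604), after cyclic loess (0.0538) and with trended, robust moderation (0.0508). The Mal call ended on leaving out any mouse but Hdh4/Q80 replicate 9 (adjusted p = 0.0604 to 0.15), after quantile (0.0503) or cyclic loess (0.0538) normalization, and with trended, robust moderation (0.0508). Of 12 astrocyte genes 9 were below 0 (median -0.08) and the list did not pass (adjusted p = 0.108), except with the mean of each gene's probe sets (0.021; adjusted p = 0.529 with an estimated correlation). Its mean difference of -0.051 became -0.079 in that setting, but -0.029 without Hdh4/Q80 replicate 8, -0.028 after quantile normalization, -0.025 after cyclic loess and -0.018 with array weights. Gfap, the astrocyte intermediate filament that rises in gliosis, read 9.16 ± 0.277 and 8.94 ± 0.204, a difference of -0.22 with an interval of -0.54 to 0.09 (-0.38 to -0.10 with 1 mouse left out). S100b and Slc4a4 had differences of -0.19 ± 0.0709 and -0.17 ± 0.0744, and Glul one of 0.20 ± 0.09, with the opposite sign on its other probe set (-0.23); 0 astrocyte genes passed adjusted over the list alone.

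Stress and energy genes gave 2 further lists shifted down. Of 18 measured chaperones and heat shock proteins 14 were below 0 (median -0.12, adjusted p = 0.00982; adjusted p = 0.651 with an estimated correlation), led by Dnajb5 (-0.21 ± 0.0894), Dnaja1 (-0.21 ± 0.0972), the endoplasmic reticulum chaperone Hspa5 (-0.26 ± 0.142) and Hspa1b (-0.15 ± 0.0829). With 1 mouse left out Dnajb5 ran from -0.29 to -0.14, Dnaja1 from -0.28 to -0.13, Hspa5 from -0.41 to -0.073 (the latter without wild-type replicate 4) and Hspa1b from -0.22 to -0.097. The call was lost without wild-type replicate 4 (adjusted p = 0.279), the mouse with the highest mean of this list, where the mean difference of -0.097 became -0.040. The call held without Hdh4/Q80 replicate 8 (0.0464, mean -0.061), with array weights (0.0348, mean -0.061) and without wild-type replicate 5 (0.000119, mean -0.15). Of 20 mitochondrial respiration genes 16 were below 0 (median -0.07, adjusted p = 0.0226; adjusted p = 0.651 with an estimated correlation), including Atp5o (-0.17 ± 0.0819), Cox7b (-0.18 ± 0.0997) and Ppargc1a, the coactivator PGC-1 alpha (-0.14 ± 0.079). With 1 mouse left out these 3 ran from -0.22 to -0.094, -0.25 to -0.10 and -0.21 to -0.090. This call was lost without wild-type replicate 4 (0.408) or Hdh4/Q80 replicate 8 (0.558), after quantile (0.141) or cyclic loess (0.155) normalization, without the dimmest 40% of probe sets (0.0763) and with array weights (0.27). Its mean difference of -0.071 became -0.034 without wild-type replicate 4, -0.015 without Hdh4/Q80 replicate 8, -0.039 and -0.035 after quantile and cyclic loess normalization and -0.029 with array weights, and -0.11 without Hdh4/Q80 replicate 9. In these lists 0 genes passed adjusted over the list alone. The 27 proteasome subunits, 21 of them below 0, missed the threshold (median -0.07, adjusted p = 0.0506), with Psmc3 at -0.22 ± 0.0931 (-0.27 to -0.13 with 1 mouse left out, and -0.037 and -0.11 on its other probe sets). They passed without wild-type replicate 5 or Hdh4/Q80 replicate 9 (adjusted p = 0.00663 and 0.00654) and after median centring (0.0496), but not with an estimated correlation (adjusted p = 0.600, 0.706 and 0.738). The mean difference of -0.060 became -0.093 and -0.11 without those mice, but 0.0070 without Hdh4/Q80 replicate 8 (adjusted p = 0.964), -0.029 without wild-type replicate 4 (0.487), -0.036 after quantile normalization (0.227), -0.032 after cyclic loess (0.254) and -0.023 with array weights (0.315). Cholesterol biosynthesis had a median of -0.0023 with 8 of 16 members below 0 (adjusted p = 0.528); Idi1, an isoprenoid isomerase, had the smallest p there (-0.36 ± 0.123; -0.44 to -0.20 with 1 mouse left out). Of 8 p53 targets and DNA damage genes 6 were below 0 (median -0.02, adjusted p = 0.445), with Gadd45a at -0.14 ± 0.0926 (-0.20 to -0.040 with 1 mouse left out). The p53 list's mean difference of -0.044 became -0.014 without Hdh4/Q80 replicate 8 and -0.018 with array weights. In the proteasome, cholesterol and p53 lists 0 genes passed adjusted over the list alone.

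Immediate early genes, which neurons induce with activity, were shifted down as a list (10 of 12 below 0, median -0.13, adjusted p = 0.0226; adjusted p = 0.651 with an estimated correlation). Egr1 was the 1 member that passed adjusted over the list alone (adjusted p = 0.0197), and its dimmer probe set had the opposite sign (0.32). That probe set read 5.332 in wild type and 5.657 in mutants, means below the lower quartile of each array (5.79 to 5.86). Its sign is therefore weak evidence against the brighter one. Nr4a1 read 8.41 ± 0.4 in wild type and 7.91 ± 0.438 in mutants, and Junb (-0.20 ± 0.135) and Dusp1 (-0.21 ± 0.164) had wide errors. With 1 mouse left out the difference ran from -0.75 to -0.33 for Nr4a1, -0.33 to -0.097 for Junb and -0.38 to -0.098 for Dusp1. The list's mean score ran from -0.15 in wild-type replicate 4 to 0.32 in wild-type replicate 6, and from -0.28 in Hdh4/Q80 replicate 8 to 0.19 in replicate 7. The list's call was lost without wild-type replicate 5 (0.0507), wild-type replicate 6 (0.365), Hdh4/Q80 replicate 8 (0.257) or replicate 9 (0.251), with array weights (0.793) and with the mean of each gene's probe sets (0.0934). Its mean difference of -0.17 became -0.048 without wild-type replicate 6, -0.071 without Hdh4/Q80 replicate 8 and 0.0053 with array weights, against -0.29 without wild-type replicate 4 and -0.31 without Hdh4/Q80 replicate 7. Within its list Egr1 lost its call without wild-type replicate 4, 5 or 6 or Hdh4/Q80 replicate 9 (adjusted p = 0.0527, 0.0791, 0.103 and 0.0678), and with the mean of its probe sets (0.978).

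The transcript with the largest difference was a marker of choroid plexus, a tissue of the brain ventricles. The choroid plexus and ependymal list was shifted up (9 of 9 above 0, median 0.14, adjusted p = 0.00384; adjusted p = 0.619 with an estimated correlation), and 0 of its members passed adjusted over the list alone (smallest adjusted p = 0.253). Ttr, transthyretin, an abundant choroid plexus product, read 8.48, 8.32 and 10.26 in wild-type replicates 4, 5 and 6 and 8.46, 10.59 and 11.24 in Hdh4/Q80 replicates 7, 8 and 9, a mean difference of 1.08 with a standard error of 0.671. Kl, encoding klotho, differed by 0.83 ± 0.44, the bicarbonate transporter Slc4a5 by 0.49 ± 0.218 and the folate receptor Folr1 by 0.32 ± 0.171. With 1 mouse left out these ran from 0.41 to 1.41, 0.28 to 0.77 and 0.14 to 0.53. The list's call was lost without Hdh4/Q80 replicate 8 (adjusted p = 0.0667) or replicate 9 (0.0531), and with array weights the list lay in the opposite direction without passing (adjusted p = 0.9005). Its mean difference of 0.35 became 0.19 without Hdh4/Q80 replicate 9, -0.099 with array weights and 0.57 without Hdh4/Q80 replicate 7. Red blood cell markers were shifted down (3 of 4 below 0, median -0.15, adjusted p = 0.039; adjusted p = 0.651 with an estimated correlation). Hba-a1 and Hbb-b2, a beta-globin (8.14 ± 0.0881 against 7.85 ± 0.0512), passed when adjusted over the list alone (adjusted p = 0.00217 and 0.00625), and held under each scaling, filter, moderation and weighting tried, with the mean of each gene's probe sets and on leaving out any 1 mouse; probe sets of near-identical globin genes can bind each other's transcripts. Alas2 and Slc4a1 had differences of -0.01 and 0.17 (0.034 to 0.26 for Slc4a1 with 1 mouse left out), and the list's call was lost without wild-type replicate 4 (0.169) or 5 (0.0701) or Hdh4/Q80 replicate 7 (0.0593) or 9 (0.286), and after quantile (0.0772) or cyclic loess (0.0989) normalization, with trended, robust moderation (0.0504) and with array weights (0.28). Its mean difference of -0.14 became -0.089 with array weights and -0.24 without the dimmest 40% of probe sets. The cortical list (7 of 8 below 0), the thalamic and hypothalamic list (4 of 10 below 0) and the endothelial list (7 of 12 below 0) did not pass (adjusted p = 0.528, 0.725 and 0.894), and 0 of their genes passed adjusted over the list alone. Tbr1, a cortical projection neuron factor, had a standard deviation of 0.98 among wild types against a group difference of -0.38. Cldn5, of endothelial tight junctions, differed by -0.21 ± 0.111 (-0.27 to -0.094 with 1 mouse left out), and Lef1, a thalamic marker, by 0.11 ± 0.0752 (0.051 to 0.16).

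**Figure D2:**
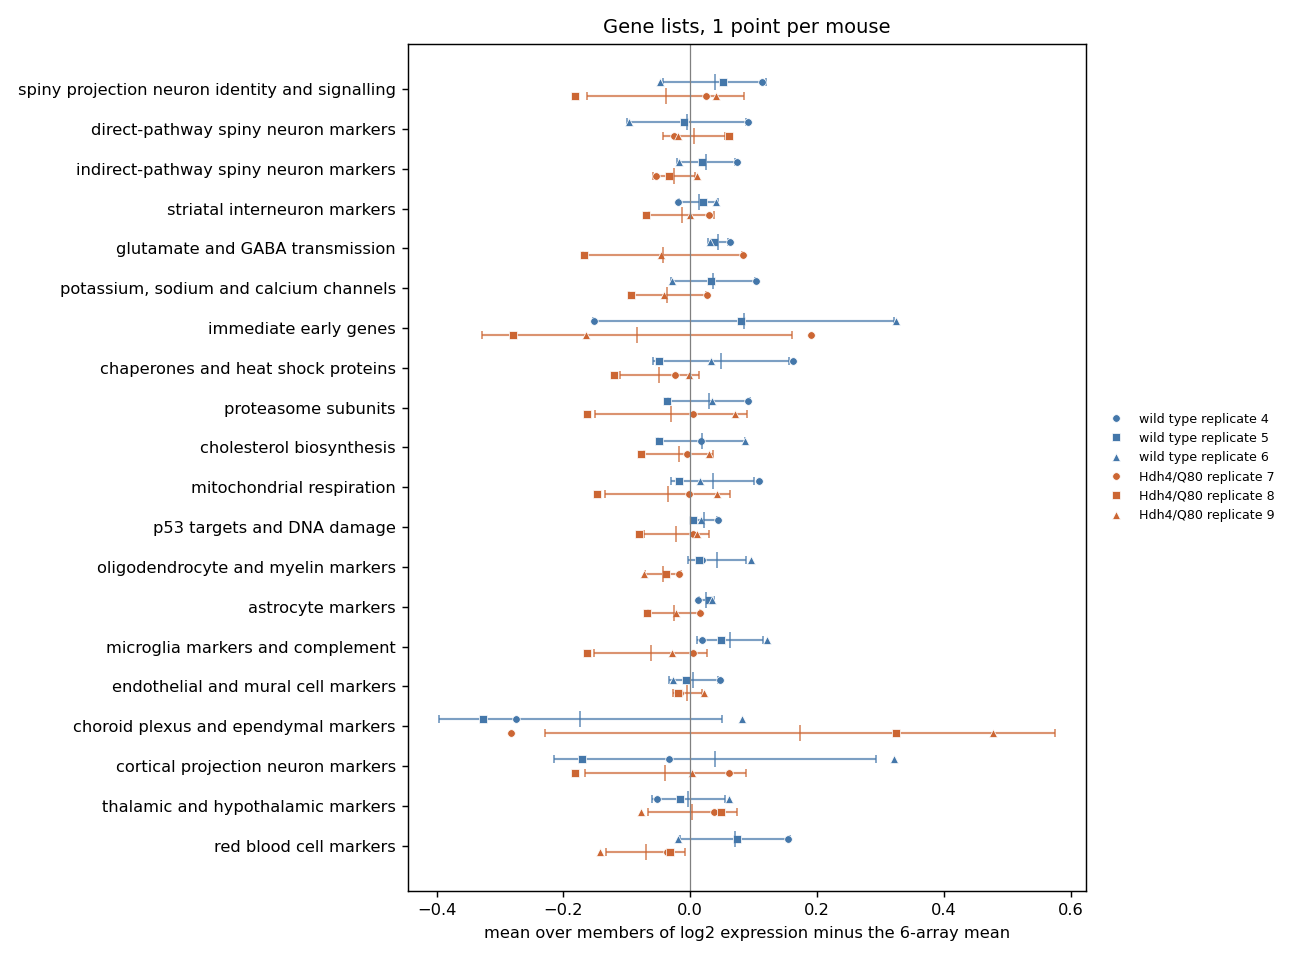
Mean over the measured members of each of the 20 gene lists of log2 expression minus that gene's mean over the 6 arrays, in each mouse; blue points are wild-type and orange points Hdh4/Q80 mice, and ticks with bars are the group mean ± SD (n = 3). The choroid plexus list spreads most, from -0.33 in wild-type replicate 5 to 0.48 in Hdh4/Q80 replicate 9, and Hdh4/Q80 replicate 8 is the lowest mouse in 13 of the 20 lists, among them 4 of the 6 called lower: immediate early (-0.28), microglia (-0.16), mitochondrial (-0.15) and chaperone (-0.12).

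In all, 7 of the 20 lists were called with camera's preset correlation of 0.01, 6 lower and 1 higher, 0 with the correlation estimated from the data and 0 with limma's fry, whose smallest adjusted p was 0.427 for a common direction and 0.189 for change in either direction. Each of the 7 calls was lost when at least 1 single mouse was left out. An exact permutation test on the mice's mean list scores cannot go below p = 0.10 with 3 against 3. The oligodendrocyte, microglia and red blood cell lists were at that value (two-sided). Any 1 list reaches it by chance with a probability of 0.10, so some of 20 lists can be there by chance alone.

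**Figure D3:**
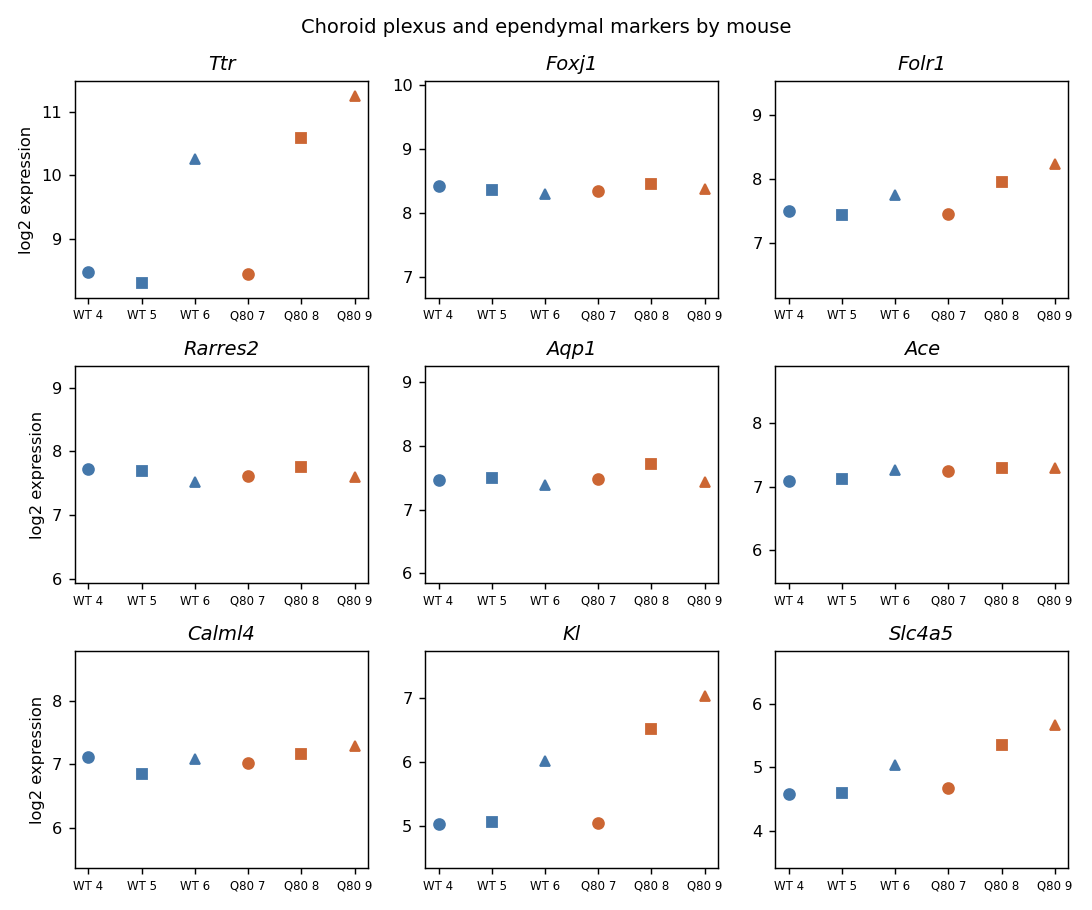
Log2 expression of the 9 measured choroid plexus and ependymal markers in each mouse (WT, wild type; Q80, Hdh4/Q80; the number is the replicate), on vertical axes of equal span. Ttr, Kl, Folr1 and Slc4a5 are higher in wild-type replicate 6 and Hdh4/Q80 replicates 8 and 9 than in the remaining mice, while Foxj1 stays between 8.29 and 8.45.

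Genes that neighbour Htt did not stand out. They were examined because a knock-in can carry flanking sequence of the embryonic stem cell strain. Of the 100 measured genes nearest to Htt in gene order, 50 on each side, 0 had an unadjusted p under 0.01, against 44 of 8136 other placed genes (0.541%; two-sided Fisher's exact p = 1, with an upper 95% limit of the odds ratio of 7.2). The neighbour with the smallest p was Rfc1, a subunit of the DNA replication clamp loader (-0.18 ± 0.0725, unadjusted p = 0.0309 in limma's test, adjusted p = 0.857).

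RNA quality measures overlapped between the groups, although Hdh4/Q80 replicates 8 and 9 were high in several of them. The 3' minus 5' log2 difference of the beta-actin control was 0.64 ± 0.0831 in wild type and 0.782 ± 0.128 in mutants (exact permutation p = 0.2, two-sided, n = 3 each), and that of Gapdh was 0.245 ± 0.0208 and 0.219 ± 0.107 (exact p = 0.7). With 3 against 3 an exact permutation test cannot go below p = 0.10, so these tests cannot show equal quality. For beta-actin, Hdh4/Q80 replicates 8 and 9 (0.858 and 0.855) lay above every wild type (0.566 to 0.730), and replicate 7 (0.634) did not. Hdh4/Q80 replicate 8 had the largest 3' minus middle difference of the 6 arrays in 4 of 5 differences over the control transcripts, and the largest 3' minus 5' difference in 1 of 4. Replicate 9 had the largest 3' minus 5' difference for Gapdh (0.330) and pyruvate carboxylase (2.16). It was also the largest against a middle probe set of pyruvate carboxylase (1.155). Wild-type replicate 4 had the largest 3' minus 5' difference for the transferrin receptor (1.23).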

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

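The comparison with random lists was chosen after seeing the data. The count of 0 probe sets and 0 genes at an adjusted p under 0.05 in limma's test was the same under every alternative run, with a smallest adjusted p of 0.0873, under array weights, where the weights ran from 0.228 (Hdh4/Q80 replicate 8) to 6.18 (replicate 7). Replicate 9 had a weight of 0.405, so values under array weights set mainly 1 mutant mouse against the wild types. The 634 probe sets at an unadjusted p under 0.05 became 338 without the dimmest 40% of probe sets, which leaves fewer to test (142 higher, 196 lower), and 1812 with array weights. Leaving out 1 mouse gave 251 (without wild-type replicate 6) to 1153 (without Hdh4/Q80 replicate 9), and 1049 without Hdh4/Q80 replicate 7. The 7 called lists became 4 after quantile normalization, 4 after cyclic loess, 3 with array weights, 0 with an estimated correlation, 0 with fry and 3 to 8 when 1 mouse was left out. Against 10000 random lists matched on brightness, 6 lists had a median outside the central 95%: the immediate early, chaperone, choroid plexus and red blood cell lists, and the transmission and channel lists, which were not called (percentiles 0.44 and 1.95). The called oligodendrocyte, microglia and mitochondrial lists lay inside it (percentiles 6.15, 5.61 and 6.17). The random lists drew each gene independently, so these percentiles do not measure the spread between mice. The brighter Htt probe set changed sign after quantile normalization (0.013) and cyclic loess (0.025), and ran from -0.052 to 0.014 with 1 mouse left out; it was called in no setting. Of 93 named probe sets, 0 were called under any alternative and 25 changed sign in at least 1. Alas2 turned to 0.0031 with quantile normalization and 0.0042 with cyclic loess. With array weights camera's direction turned for the choroid plexus (adjusted p = 0.9005) and transmission (0.754) lists. The mean difference alone turned for the spiny neuron (0.0022), interneuron (0.0037), channel (0.00021) and immediate early (0.0053) lists, and the sign turned for Penk (-0.035), Cnr1 (0.18), Rgs4 (0.063), Arpp19 (0.0042), Eya1 (-0.032), Isl1 (0.026), Nos1 (0.095), Kcnj4 (0.0029), Dusp1 (0.032), Gadd45g (0.030), Sesn1 (0.019), Slc4a5 (-0.047), Kl (-0.31), Folr1 (-0.088), Cux2 (0.018) and Alas2 (0.046). With the mean of each gene's probe sets it turned for Penk (-0.10), Ptpn5 (0.018) and Glul (-0.011) and for the direct-pathway and thalamic lists (adjusted p = 0.993 for each), and without the dimmest probe sets camera's direction, not the mean (-0.0085), turned for the endothelial list (0.781). With 1 mouse left out, differences crossed 0 for Penk (-0.032 to 0.078), Tac1 (-0.13 to 0.21), Drd2 (-0.15 to 0.028), Cnr1 (-0.20 to 0.092), Sfxn1 (-0.16 to 0.067), Eya1 (-0.049 to 0.11), Isl1 (-0.078 to 0.0073), Sesn1 (-0.16 to 0.079), Mdm2 (-0.046 to 0.015), Tbr1 (-0.82 to 0.15), Cux2 (-0.18 to 0.025), Hcrt (-0.10 to 0.011) and Alas2 (-0.045 to 0.016). Lists whose camera direction turned on leaving out a mouse had adjusted p-values of 0.117 to 0.783 (cholesterol), 0.0507 to 0.964 (cortical), 0.261 to 0.783 (direct pathway), 0.237 to 0.988 (thalamic) and 0.594 to 0.964 (endothelial); the mean alone turned for the interneuron (0.0010) and proteasome (0.0070) lists without Hdh4/Q80 replicate 8. The differences of 71 of the 93 named probe sets moved by over 1.5 times on leaving out at least 1 mouse, 50 of them without Hdh4/Q80 replicate 8. With an estimated correlation 0 lists were called in any of these settings (smallest adjusted p = 0.264). Neighbours of Htt gave Fisher's exact p of 0.132 to 1 over the other windows, thresholds and mice left out. The cause of these movements was not tested, apart from the fewer probe sets under the brightness filter. No paired analysis was possible because the groups share no replicate numbers. Signal over background was not analysed here, so no limit from dim signal can be given.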

Other observations

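The splits of the 6 mice for the unadjusted count and for the gene lists were set before their results were seen; the splits for the adjusted count and the tests on estimated correlation, on lists with and without replicate 8, on degraded RNA, on brightness, on choroid plexus tissue and on genotype were chosen only after the results, or part of them, had been seen. Histone and haemoglobin probe sets were noticed in the ranking of p-values and grouped afterwards. Of 31 histone probe sets, 6 had an unadjusted p under 0.05 in the lower direction and 1 in the higher (7 and 1 after quantile normalization or cyclic loess), with a median difference of -0.03. The linker histone H1f2 differed by -0.35 ± 0.0805 (SE), and a probe set assigned jointly to 12 genes of the H3 family by -0.38 ± 0.0786. Another probe set assigned to the same 12 genes differed by -0.11 ± 0.0755. Probe sets assigned jointly to some of these genes differed by 0.15 ± 0.117 and -0.042 ± 0.105. Of 10 haemoglobin probe sets, 4 had an unadjusted p under 0.05 in the lower direction and 0 in the higher (3 and 0 after quantile normalization or cyclic loess), including 1 assigned jointly to 4 genes (-0.44 ± 0.0929). Another, much dimmer probe set assigned to the same 4 genes differed by -0.11 ± 0.0782. None of these passed limma's adjusted test (smallest adjusted p = 0.857, and 0.842 to 0.853 under the other scalings).

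Fos, widely used as a marker of recent neuronal activity, read 4.98, 6.46 and 6.52 in wild-type replicates 4, 5 and 6 and 6.48, 5.13 and 4.87 in Hdh4/Q80 replicates 7, 8 and 9 on its probe set of wider range. Each genotype thus held values near 5 and values above 6. Its other probe set read between 5.24 and 5.75. The gene was chosen after its values were seen.

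Splitting the 6 mice in other ways gives 10 splits into 3 and 3, too few for a share under 0.05. At an adjusted p under 0.05 the real split gave 0 probe sets and the highest other split 3; with a real count of 0, all 10 splits give as many by construction, so this count tests nothing. At an unadjusted p under 0.05 the real split gave 634 probe sets and the highest other 1308, and 3 of the 10 splits, the real one included, gave as many. The split with 1308 set wild-type replicates 4 and 6 with Hdh4/Q80 replicate 9 against the remaining mice. For the gene lists the real split called 7 and the highest other 7, and 3 of the 10 splits gave as many.

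The 7 called gene lists were weighed against 2 technical explanations. A candidate explanation is that members of a list vary together between mice of 1 genotype, beyond the preset correlation of 0.01. Estimated correlations of the called lists ran from 0.083 to 0.535, and 0 lists were called once the correlation was estimated. That loss cannot decide the question, because camera then also rests on the 4 residual degrees of freedom. The astrocyte list's estimated correlation was -0.0048, below the preset one, yet its unadjusted camera p rose from 0.065 to 0.124. Hdh4/Q80 replicate 8 alone is argued against for the oligodendrocyte and red blood cell lists, since these 2 were still called without it and kept 103% and 114% of their mean difference. For the others this stays open: the chaperone and microglia lists were still called but kept 63.2% and 59.8%, and of the lists lost, choroid plexus kept 78.1%, immediate early genes 42.1% and mitochondrial respiration 21.2%. An effect of genotype on these lists also stays open.

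Hdh4/Q80 replicate 8 stood apart from the other mice, with a standard deviation of its deviations from the 6-array gene means of 0.17, against 0.0684 to 0.118 for the others. Degraded RNA stays open: of 9 differences between the 3' end and the middle or 5' end of 4 control transcripts, replicate 8 was the largest in 5, which were 4 of 5 against the middle but 1 of 4 against the 5' end (0.833 and 0.667 by chance). A compressed range of brightness is argued against as the whole account of this spread, as 8.01% of the variance of its deviations followed a smooth curve in brightness. That share includes the scatter of single genes. Its deviations fell with brightness more steeply than on the other arrays (slope -0.028, against -0.0033 to 0.0165). Its values also had the smallest SD over probe sets (1.74, against 1.77 to 1.81). A part for brightness in the list means stays open. Against brightness-matched random lists, the called mitochondrial, oligodendrocyte and microglia medians lay at percentiles 6.17, 6.15 and 5.61, inside the central range. The chaperone, red blood cell, immediate early and choroid plexus medians lay outside it (0.02, 0.66, 0 and 100). Quantile normalization ended the mitochondrial, oligodendrocyte and red blood cell calls (camera adjusted p = 0.141, 0.101 and 0.0772) and left the others. The random lists drew genes independently, so they cannot decide this. What else sets this mouse apart was not tested, and no biological explanation was tested.

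For the choroid plexus markers, an effect of genotype stays open: the 3 mutants lay above the 3 wild types in 0 of 9 markers, where chance gives 0.45, while all 9 mean differences were above 0. Choroid plexus tissue carried along in some dissections is also a candidate explanation. The order seen in Ttr, taken as the reference after its values were seen (wild-type replicate 6 highest of its group at 10.26, Hdh4/Q80 replicate 7 lowest of its group at 8.46), recurred in 4 of the 8 other markers (Folr1, Ace, Kl and Slc4a5), where chance gives 0.889. The other 4 did not follow it, fewer than the 6 the test asked for, so this explanation stays open; 0 of the markers are in another list, and which of them the striatum itself expresses was not analysed here.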
